A study of Arabidopsis thaliana with 18 samples.

How the data were processed

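RNA of whole seedlings was measured in 18 libraries, 3 in each of 6 groups: wild type, cry1cry2 and BIC1ox, each kept in the dark or given 2 h of blue light. Per the labels, the seedlings were of the Columbia background and 6 d old, RNA was taken with TRIZOL, strand-specific libraries were made by the dUTP method and sequenced on an Illumina HiSeq 2500, and reads were aligned with TopHat2 2.0.11 to the TAIR10 genome. The labels name no mutant alleles. The values analysed were those of 1 deposited table of 25456 genes.

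The deposited FPKM values (reads scaled to gene length and to the mapped reads of the library) were made by the authors; the program that counted the reads and how reads shared by overlapping genes or by paralogs were counted are not given in the sources used here. The fold changes in the table were made by the authors as blue-light over dark FPKM of the same repeat, and 0 of them differed from that ratio when recomputed. The p-values and false discovery rates (FDR) of blue light against dark, 1 pair of columns per genotype, were also made by the authors, with a test that is not stated. They were used only to count the authors' calls.

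Low FPKM values were whole multiples of a step set by gene and library. From these steps whole reads were recovered for 100% of values (tolerance 1e-06 reads). Recovered reads in genes ranged from 17472415 to 30742232 per library, 94.7 to 96.9% of the reads that the FPKM scale implies. FPKM summed to 651947 to 720352 per library, and the 20 highest genes held 6.47 to 8.53% of the sum. Reads of 1 library are not independent molecules, so a count of 0 reads, which allows up to 3 reads at this depth, covers counting error only. The table held 0 genes of the organelles and 103 microRNA genes. Gene names, chromosomes and the order of genes came from the TAIR10.1 annotation, which held 25341 of the genes. The gene lengths implied by the FPKM steps equalled the exon lengths of that annotation for 3929 genes (15.4%), and no base positions are given since the builds differ. The reads of genes that overlap others remain uncertain.

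The 6 groups were fitted together with limma 3.58.1 in R 4.3.3 as a cell-means model of log2(FPKM + 1), with empirical Bayes moderation and a trend (residual df 12, prior df 4.04). Genes with FPKM of at least 1 in at least 3 libraries were tested, 19131 in all. Calls had a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes of a contrast. There were 9 contrasts between 2 groups and 3 differences between light responses. The fit assumes that all groups vary alike. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

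In each contrast 27 gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Member counts were also made with p adjusted over the list alone. The lists named 428 genes, of which 427 were in the table (PDF1.2 was not). They covered photoreceptors, early light genes and regulators, PIF factors, shade and PIF targets, light-harvesting proteins, photosystems and Rubisco, chlorophyll, carotenoids, flavonoids, the clock, flowering time, auxin, gibberellin, brassinosteroid, cell wall expansion, cytokinin, jasmonate, abscisic acid and cold, heat shock, oxidative stress, pathogen defence, dark-induced genes, nitrate assimilation, the cell cycle, and root, seed and stomatal markers of other tissues of a whole seedling. The genes singled out followed a rule. In every contrast between 2 groups these were CRY1, CRY2, BIC1 and BIC2, and the 10 largest rises and 10 largest falls among called genes with a mean FPKM of at least 5 in the higher group and no overlap of replicates. From each list described, up to 4 members with the smallest adjusted p were added. For differences between light responses they were the 10 genes with the smallest adjusted p. The same genes could be named in another contrast, and the text names some of them only.

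The fit was tested on simulated data, drawn with the gene means of wild type in the dark, the depths of the 18 libraries and the fitted spread, with known changes put into 200 genes of wild type in blue light (18361 genes tested). It called 17.9% of the genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold. It also called 11 unchanged genes, 7.80% of its calls, and 0 genes in the light response of cry1cry2, where no change was put in.

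The labels number the replicates 1 to 3 in each group and do not say whether equal numbers mark a shared culture or day. By the rule used, equal numbers paired the libraries only in the light response of cry1cry2, where the deviations of equally numbered libraries from their group means correlated across genes with r = 0.108, 0.332 and 0.176. Values with the replicate number as a block are given with the alternatives. No pair of replicates looked like 1 library deposited more than once.

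Results were recomputed with a pseudocount of 0.1, a minimum of FPKM 5, no minimum, the replicate block, each replicate left out, fits of the groups of a contrast alone, median-ratio scaling, quantile normalization, an absolute log2 fold change of at least 1, and the estimated correlation. Alternatives added after seeing the data were limma voom on the recovered reads with median-ratio library sizes, removal of a gene-length trend per library, leaving out the 2 libraries that stood apart (dark replicate 1 of wild type and blue-light replicate 2 of BIC1ox), a replicate block within each genotype, and wild-type controls split between the overlap's comparisons. Limma voom called 10506 genes for the light response of wild type, 3430 for cry1cry2 and 5153 for BIC1ox.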

Results

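Messenger RNA was measured by strand-specific sequencing in 18 libraries of Arabidopsis thaliana seedlings of the Columbia background, 6 d old. The seedlings were of 3 genotypes. Beside wild type there were the cry1cry2 double mutant, which lacks the blue-light receptors cryptochrome 1 and cryptochrome 2, and BIC1ox. BIC1ox overexpresses BIC1 (BLUE-LIGHT INHIBITOR OF CRYPTOCHROMES 1), a protein that inhibits CRY2 dimerization. Each genotype was kept in the dark or given 2 h of blue light, which made 6 groups of 3 libraries. Reads assigned to genes ranged from 17472415 to 26301588 in wild type in the dark and from 19615447 to 30742232 in wild type in blue light. They ranged from 18718947 to 24653254 in cry1cry2 in the dark, from 23606437 to 26017472 in cry1cry2 in blue light, from 21611275 to 23580101 in BIC1ox in the dark and from 21448793 to 26112495 in BIC1ox in blue light. The design asks which genes respond to blue light, how much of that response is lost without cryptochromes, and whether an excess of BIC1 acts on the same genes. Expression levels are given as the mean FPKM ± SD of 3 libraries. Log2 fold changes are on the scale of log2(FPKM + 1), which understates the change of genes with low values, and are given ± SE from limma. The replicates are not stated to be separate cultures, so the p-values measure the spread between these samples, which may be technical.

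The genes named by the genotypes were examined first. CRY1 (AT4G08920, chromosome 4) had 34.2 ± 3.99 FPKM in wild type in the dark and 24.9 ± 0.390 in blue light. In cry1cry2 it had 0.0232 ± 0.00986 and 0.0686 ± 0.0563 FPKM, from 1 to 8 reads per library. CRY2 (AT1G04400, chromosome 1) had 69.4 ± 9.01 and 43.2 ± 3.19 FPKM in wild type and 0.0257 ± 0.0320 and 0.111 ± 0.0864 in cry1cry2, from 0 to 13 reads per library. BIC1 (AT3G52740, chromosome 3) had 0.512 ± 0.377 FPKM in wild type in the dark and 2663 ± 345 in BIC1ox in the dark. In blue light it had 24.8 ± 4.74 and 3381 ± 201 FPKM. Both cryptochrome genes were expressed in BIC1ox, CRY1 at 42.3 ± 5.96 and 41.1 ± 8.10 FPKM and CRY2 at 68.9 ± 4.44 and 53.8 ± 1.65 in the dark and in blue light. The 18 libraries thus carried the expression of CRY1, CRY2 and BIC1 that their labels name.

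Blue light raised BIC1 in wild type (log2 fold change 4.11 ± 0.18, limma adjusted p = 8.5e-11). It also raised BIC1 in cry1cry2, to 25 ± 2.33 FPKM (3.66 ± 0.18, adjusted p = 7.5e-10). The BIC1 levels of these 2 genotypes in blue light differed by 0.02 ± 0.18 (adjusted p = 0.93), and their light responses differed by -0.45 ± 0.25 (adjusted p = 0.18). In BIC1ox the light response of BIC1 was 0.35 ± 0.18 (limma adjusted p = 0.15), and its difference from the wild-type response was -3.76 ± 0.25 (adjusted p = 1.4e-06). BIC2 (AT3G44450, chromosome 3), a close relative of BIC1, rose in wild type from 0.472 ± 0.208 to 8.69 ± 0.720 FPKM (2.73 ± 0.15, limma adjusted p = 9.8e-10). It rose in cry1cry2 to 4.84 ± 0.445 FPKM (2.15 ± 0.15, adjusted p = 3.7e-08) and in BIC1ox to 5.15 ± 1.22 (2.08 ± 0.15, adjusted p = 3.6e-08). In blue light BIC2 was lower in cry1cry2 than in wild type (-0.73 ± 0.15, adjusted p = 0.0015). It was also lower in BIC1ox (-0.67 ± 0.15, adjusted p = 0.0071), though with an adjusted p of 0.071 when the fit held these 2 groups alone. CRY2 fell in wild type after blue light (-0.67 ± 0.11, limma adjusted p = 8.9e-05). CRY1 fell in wild type as well (-0.43 ± 0.14, adjusted p = 0.012), a call that was lost after median-ratio scaling (-0.15, adjusted p = 0.36). The fall of CRY2 in BIC1ox (-0.35 ± 0.11, adjusted p = 0.024) was lost with that scaling too (-0.22, adjusted p = 0.20). It was also lost without dark replicate 1 or 2 or blue-light replicate 1 of BIC1ox (adjusted p = 0.095, 0.060 and 0.081).

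**Figure D1:**
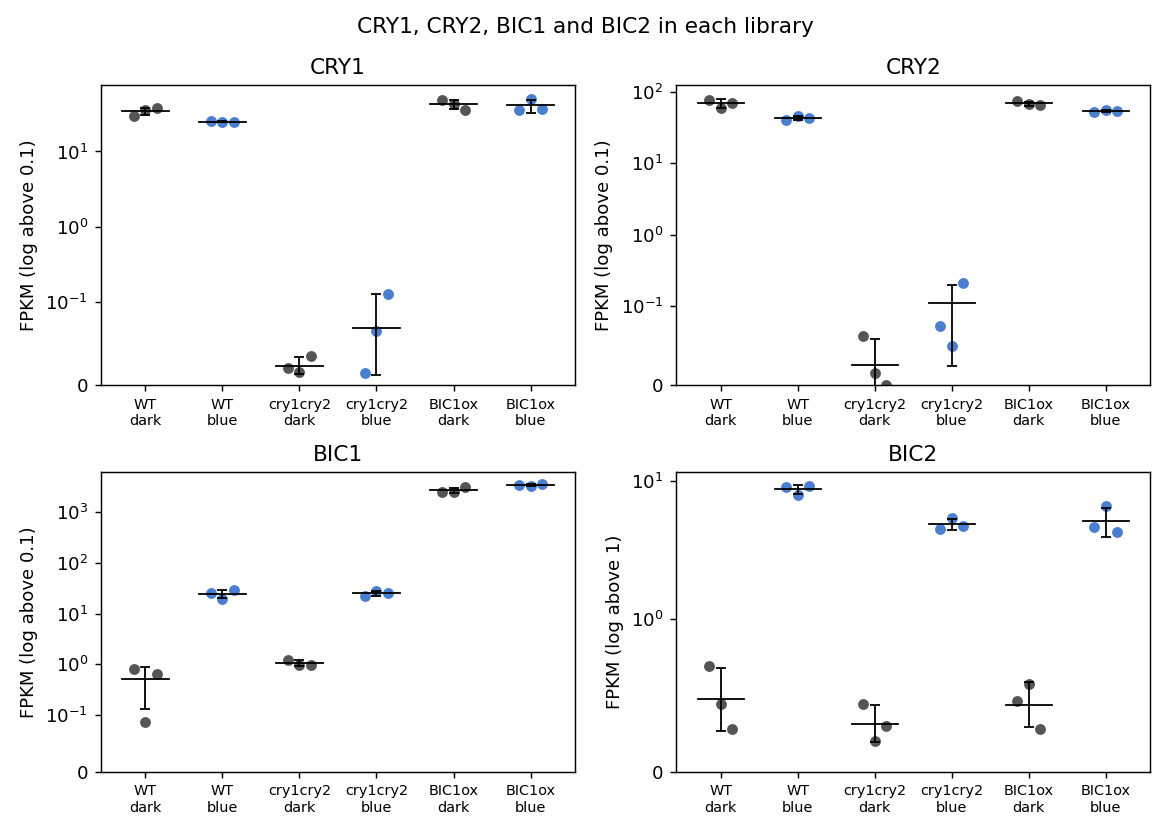
FPKM of CRY1, CRY2, BIC1 and BIC2 in each of the 18 libraries (points), with the mean (bar) and SD (error bar, n = 3) of each group; the vertical axis is logarithmic above 0.1 FPKM (above 1 for BIC2) and linear below. CRY1 and CRY2 stay below 1 FPKM in the cry1cry2 libraries, and BIC1 has a mean of 2663 FPKM in BIC1ox in the dark and 3381 in blue light.

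The large rises in wild type after 2 h of blue light included those of 3 AP2/ERF transcription factor genes. RRTF1 (AT4G34410) rose from 0.660 ± 0.494 to 704 ± 209 FPKM (8.72 ± 0.44, limma adjusted p = 3.7e-10). ORA47, an activator of jasmonate synthesis genes, rose by 6.76 ± 0.37 and DDF1 by 6.70 ± 0.42. WRKY40, a transcription factor of defence responses, rose by 7.27 ± 0.47, the methionine sulfoxide reductase gene MSRB6 by 6.75 ± 0.16 and the calmodulin-like gene CML37 by 6.47 ± 0.48. The B-box gene BBX17 fell from 174 to 3.06 ± 1.54 FPKM (-5.50 ± 0.34, limma adjusted p = 3.4e-09). A large fall was also that of the kinase gene SNRK2.5 (-4.80 ± 0.18). PORB, a protochlorophyllide oxidoreductase of chlorophyll synthesis, fell from 864 ± 139 to 38 ± 9.04 FPKM (-4.48 ± 0.33).

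Among the gene lists fixed before the data were examined, the flavonoid, early light, jasmonate, heat shock, oxidative stress, pathogen and abscisic acid lists were called higher in wild type. Flavonoid and anthocyanin genes rose in 15 of 16 members (15 adjusted over the list), among them F3H (5.23), CHI (AT3G55120, 3.19) and the anthocyanin regulator MYB75 (4.40). The flavonoid median was 2.66 (camera adjusted p = 1.5e-13, and 0.039 with an estimated correlation). Early light-induced genes and light-signalling regulators rose in 18 of 25 members and fell in 3 (18 and 3 adjusted over the list), with BBX32 at 4.2 and the plastid sigma factor gene SIG5 at 4.27. The early light median was 2.03 (camera adjusted p = 2.1e-11, and 0.015 with an estimated correlation). Jasmonate synthesis and response genes rose in 14 of 14 members (14 adjusted over the list), among them AOS (4.45) and AOC2 (4.29), of jasmonate synthesis, and the repressor genes JAZ1 (6.10) and JAZ5 (6.23). The jasmonate median was 4.90 (camera adjusted p = 1.5e-13, and 0.16 with an estimated correlation). Heat shock genes rose in 8 of 12 members and fell in 1 (8 and 1 adjusted over the list), with HSP70 at 3.86 and HSFA2 at 3.66. The heat shock median was 2.21 (camera adjusted p = 8.6e-06, and 0.26 with an estimated correlation). Oxidative stress genes rose in 7 of 12 members and fell in 2 (7 and 2 adjusted over the list), with ZAT10 at 5.81 and the NADPH oxidase gene RBOHD at 3.27. The oxidative stress median was 0.79 (camera adjusted p = 0.0037, and 0.27 with an estimated correlation). Pathogen defence genes rose in 4 of 8 members (4 adjusted over the list), with WRKY33 at 4.38. The pathogen defence median was 0.65 (camera adjusted p = 0.012, and 0.47 with an estimated correlation). That call was lost with a minimum of FPKM 5 (0.48, adjusted p = 0.061). Abscisic acid and cold genes rose in 6 of 12 members and fell in 4 (6 and 4 adjusted over the list, 7 and 1 with median-ratio scaling), with RD29A at 2.60 and ABI2 at -1.49. The abscisic acid median was 0.55 (camera adjusted p = 0.029, and 0.56 with an estimated correlation). It was lost without blue-light replicate 1 (median 0.36, adjusted p = 0.10; 0.93 without replicate 3) and with median-ratio scaling (0.85, adjusted p = 0.073).

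The dark-induced, shade, auxin and cytokinin lists were called lower in wild type. Dark-induced and sugar-starvation genes fell in 15 of 16 members and rose in 1 (15 and 1 adjusted over the list), including the asparagine synthetase gene ASN1 (-2.23) and the sugar transporter gene STP1 (-1.77). The dark-induced median was -1.97 (camera adjusted p = 8.6e-06, and 0.13 with an estimated correlation). Shade and PIF target genes fell in 11 of 15 members (11 adjusted over the list), among them YUC8, of auxin synthesis (-2.09), HAT1 (-2.62) and PAR1 (-4.37). The shade median was -1.65 (camera adjusted p = 0.00068, and 0.20 with an estimated correlation). Auxin genes fell in 22 of 35 members and rose in 5 (23 and 5 adjusted over the list), with TAA1 at -2.50, SAUR19 at -3.56 and GH3.6, which conjugates auxin, at 2.27. The auxin median was -1.64 (camera adjusted p = 0.0026, and 0.47 with an estimated correlation). Cytokinin response regulators fell in 8 of 8 members (8 adjusted over the list, 5 with median-ratio scaling), among them ARR7 (-2.0) and ARR9 (-1.22). The cytokinin median was -1.0 (camera adjusted p = 0.015, and 0.26 with an estimated correlation). The light-harvesting, photosystem, clock and carotenoid lists were called higher. Of 25 chlorophyll synthesis genes 5 rose and 10 fell (the same adjusted over the list), with a median of -0.44 (camera adjusted p = 0.91). Light-harvesting genes rose in 10 of 21 members and fell in 3 (10 and 3 adjusted over the list, 10 and 1 with median-ratio scaling), led by LHCB1.1 (3.68) and LHCA1 (2.48). The light-harvesting median was 0.43 (camera adjusted p = 0.0037, and 0.67 with an estimated correlation). Photosystem core and Rubisco small subunit genes rose in 7 of 25 members (5 adjusted over the list, 15 with median-ratio scaling). The photosystem median was 0.53 (camera adjusted p = 0.0037, and 0.67 with an estimated correlation). Circadian clock genes rose in 11 of 23 members and fell in 5 (12 and 7 adjusted over the list, 13 and 3 with median-ratio scaling), with LNK1 at 2.66, GI at 1.64 and RVE2 at -2.36. The clock median was 0.32 (camera adjusted p = 0.0076, and 0.47 with an estimated correlation). Carotenoid genes rose in 4 of 12 members and fell in 2 (4 and 2 adjusted over the list, 7 and 1 with median-ratio scaling), with BCH2 at 2.59. The carotenoid median was 0.39 (camera adjusted p = 0.043, and 0.67 with an estimated correlation). This call was lost without dark replicate 2 (median 0.35, adjusted p = 0.097) or blue-light replicate 3 (0.26, adjusted p = 0.077) and with median-ratio scaling (0.66, adjusted p = 0.057). The light-harvesting median was 0.13 without dark replicate 3, the photosystem median 0.29 without blue-light replicate 3, and the clock median 0.59 without that library and 0.51 without dark replicate 2.

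Of 19131 genes tested, limma called 11618 changed by blue light in wild type, 3735 higher and 7883 lower. The split depended on the scaling: with median-ratio scaling 10447 genes were called, 5380 higher and 5067 lower. On the deposited FPKM scale the median log2 fold change of all genes was -0.25 in wild type, so that a gene with a change of that size moved with the bulk.

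The cry1cry2 seedlings still responded to blue light. ELIP1, the early light-induced protein gene, rose from 7.46 ± 1.84 to 520.5 ± 141 FPKM (5.93 ± 0.38, limma adjusted p = 1.5e-08). The flavonoid enzyme genes CHS and F3H rose by 4.71 ± 0.23 and 4.0 ± 0.12, and the B-box gene BBX25 by 3.90 ± 0.24. MSRB6 rose by 4.52 ± 0.16, RUP2, a repressor of UV-B signalling, by 4.26 ± 0.26, and the Rubisco small subunit gene RBCS1B by 3.87 ± 0.43. BBX17 fell (-4.18 ± 0.34), and so did the cell wall enzyme gene XTH15 (-3.92 ± 0.28), the dark-inducible DIN1 (-3.57 ± 0.35) and the branched-chain aminotransferase gene BCAT2 (-3.52 ± 0.26). RRTF1 had 2.34 ± 1.19 FPKM in the dark and 3.99 ± 0.489 in blue light (0.63 ± 0.43, limma adjusted p = 0.37).

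In cry1cry2 the flavonoid genes rose in 14 of 16 members (14 adjusted over the list). The median flavonoid change was 2.35 (camera adjusted p = 1.2e-20, and 0.0052 with an estimated correlation). Early light genes and regulators rose in 18 of 25 members and fell in 3 (18 and 3 adjusted over the list), with BBX32 at 4.22 and SIG5 at 3.72. The median early light change was 1.80 (camera adjusted p = 2.1e-18, and 0.0017 with an estimated correlation). Dark-induced genes fell in 15 of 16 members and rose in 1 (15 and 1 adjusted over the list), with ASN1 at -3.49 and STP1 at -2.18. The median dark-induced change was -1.77 (camera adjusted p = 8.6e-15, and 0.0052 with an estimated correlation). Shade and PIF target genes fell in 12 of 15 members (12 adjusted over the list), with ATHB2 at -2.51. The median shade change was -1.06 (camera adjusted p = 7.8e-09, and 0.018 with an estimated correlation). Clock genes rose in 11 of 23 members and fell in 1 (12 and 1 adjusted over the list), with LNK1 at 2.23 and LHY at 1.23. The median clock change was 0.50 (camera adjusted p = 5.1e-06, and 0.22 with an estimated correlation). Light-harvesting genes rose in 8 of 21 members (8 adjusted over the list). The median light-harvesting change was 0.67 (camera adjusted p = 1.1e-05, and 0.68 with an estimated correlation). Heat shock genes rose in 4 of 12 members (4 adjusted over the list), with HSP70 at 2.98. The median heat shock change was 0.32 (camera adjusted p = 6.1e-05, and 0.34 with an estimated correlation). Of 14 jasmonate genes limma called 0 in cry1cry2, with 2 at unadjusted p under 0.05 and 0 by limma voom on recovered reads. Their median was 0.44 (camera adjusted p = 0.058). The heat shock median was 0.20 without dark replicate 3. In all, limma called 3538 genes changed, 1577 higher and 1961 lower, or 3383 with median-ratio scaling, 1824 higher and 1559 lower. The count was 5370 when the fit held the 6 cry1cry2 libraries alone.

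The large rises in BIC1ox included those of RRTF1, ORA47, DDF1 and ERF13. RRTF1 went from 0.413 ± 0.201 to 558 ± 338 FPKM (8.36 ± 0.44, limma adjusted p = 1.4e-09). ORA47, DDF1 and ERF13 rose by 8.18 ± 0.37, 6.46 ± 0.42 and 5.75 ± 0.48, and CML37 and ELIP1 by 5.92 ± 0.48 and 5.91 ± 0.38. Large falls included those of DIN1 (-4.02 ± 0.35), BBX17 (-3.77 ± 0.34), BCAT2 (-3.72 ± 0.26), the inositol oxygenase gene MIOX2 (-3.51 ± 0.18) and XTH15 (-3.42 ± 0.28).

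Light-harvesting genes of BIC1ox rose in 17 of 21 members (18 adjusted over the list), led by LHCB1.1 (5.04) and LHCA1 (3.27). The light-harvesting list had a median of 1.81 (camera adjusted p = 2.1e-13, and 0.22 with an estimated correlation). Photosystem and Rubisco genes rose in 20 of 25 members (21 adjusted over the list), with RBCS1B at 5.0 and PSAH2 at 2.71. The photosystem list had a median of 1.54 (camera adjusted p = 1.9e-12, and 0.24 with an estimated correlation). Chlorophyll synthesis genes rose in 13 of 25 members and fell in 3 (13 and 3 adjusted over the list), with rises of HEMA1 (2.92) and PORC (2.55) and a fall of PORA (-2.41). The chlorophyll list had a median of 0.94 (camera adjusted p = 1.0e-05, and 0.46 with an estimated correlation). Carotenoid genes rose in 6 of 12 members (8 adjusted over the list), including PSY (2.19). The carotenoid list had a median of 0.93 (camera adjusted p = 1.5e-06, and 0.24 with an estimated correlation). Jasmonate genes rose in 12 of 14 members (14 adjusted over the list), with JAZ1 at 3.96, AOS at 2.95 and MYC2, a transcription factor of jasmonate signalling, at 2.60. The jasmonate list had a median of 2.81 (camera adjusted p = 1.9e-11, and 0.15 with an estimated correlation). Blue-light replicate 2 of BIC1ox stood apart in the jasmonate and light-harvesting lists. Its mean log2(FPKM + 1) was 3.87 over the jasmonate list, against 5.87 and 5.81 in its group mates, and 9.83 over the light-harvesting list, against 8.83 and 8.59. Without it the chlorophyll median was 0.60. Flavonoid genes rose in 13 of 16 members (14 adjusted over the list). The flavonoid list had a median of 2.12 (camera adjusted p = 1.4e-14, and 0.019 with an estimated correlation). Early light genes and regulators rose in 18 of 25 members and fell in 3 (19 and 3 adjusted over the list). The early light list had a median of 1.34 (camera adjusted p = 3.2e-13, and 0.0079 with an estimated correlation). Dark-induced genes fell in 15 of 16 members and rose in 1 (15 and 1 adjusted over the list), with DIN2 at -3.51. The dark-induced list had a median of -2.05 (camera adjusted p = 3.8e-11, and 0.019 with an estimated correlation). Auxin genes fell in 24 of 35 members and rose in 3 (27 and 3 adjusted over the list). The auxin list had a median of -1.72 (camera adjusted p = 5.7e-09, and 0.15 with an estimated correlation). Shade and PIF target genes fell in 11 of 15 members (12 adjusted over the list). The shade list had a median of -1.72 (camera adjusted p = 6.2e-08, and 0.030 with an estimated correlation). Limma called 5836 genes changed in BIC1ox, 2396 higher and 3440 lower. With median-ratio scaling it called 5262, 2946 higher and 2316 lower (median of all genes -0.12 without it).

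**Figure D2:**
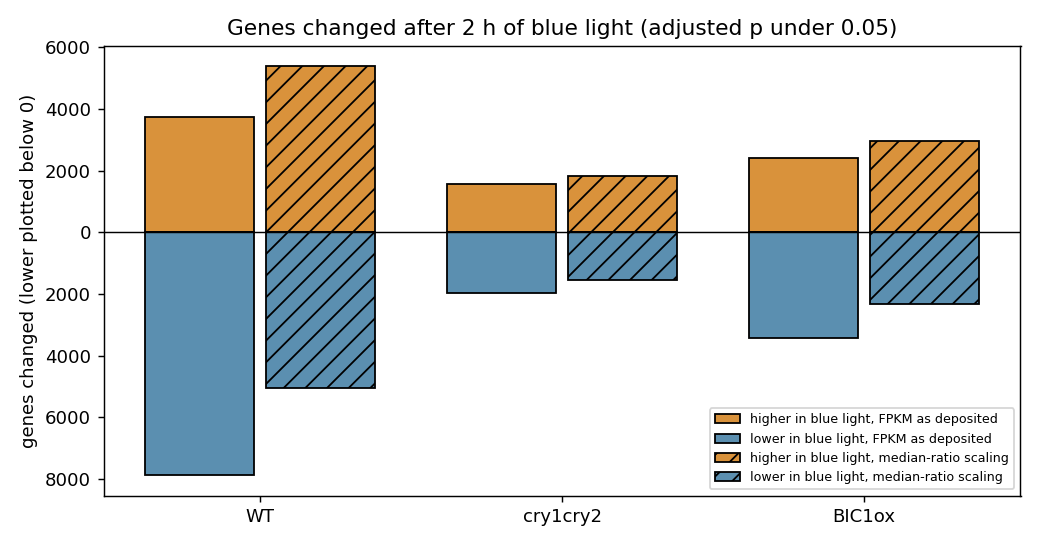
Number of genes called changed by 2 h of blue light (limma, adjusted p under 0.05) in each genotype, higher genes above 0 and lower genes below, on the deposited FPKM scale and after median-ratio scaling (hatched). Wild type had 11618 changed genes, BIC1ox 5836 and cry1cry2 3538, and the share of higher genes rose with median-ratio scaling in each genotype. The authors' test reverses the order of BIC1ox and cry1cry2.

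**Figure D3:**
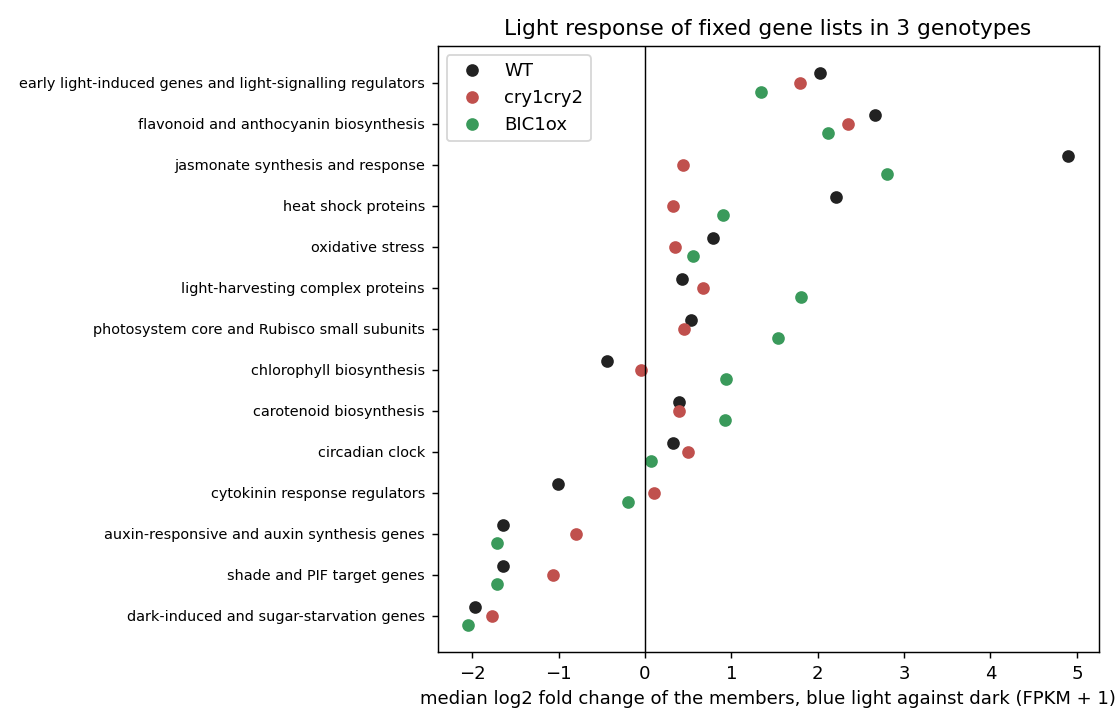
Median log2 fold change (FPKM + 1, blue light against dark) of the members of 14 gene lists, 1 point per genotype. The jasmonate list sits at 4.90 in wild type, 2.81 in BIC1ox and 0.44 in cry1cry2, while the medians of the flavonoid list lie between 2.12 and 2.66.

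The light responses were then compared between genotypes. In wild type 4549 genes changed by at least 1 on the log2 scale, 1967 up and 2582 down (4066, 2626 up and 1440 down, with median-ratio scaling). Taken in the wild-type direction, their median response was 1.43 in wild type, 0.40 in cry1cry2 and 0.62 in BIC1ox. The median ratio to the wild-type response was 0.261 in cry1cry2 and 0.408 in BIC1ox. The sign was that of wild type for 84.5% of them in cry1cry2 and 88.3% in BIC1ox. By limma's test of the difference, the response was called smaller than in wild type for 3027 of these genes in cry1cry2 and 2470 in BIC1ox. Choosing genes on their wild-type values raises the wild-type median. In libraries not used to choose the genes it averaged 1.35 (1.17 to 1.64) over 9 ways of leaving out 1 dark and 1 blue-light library.

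For cry1cry2 against wild type, the difference in light response was negative for RRTF1 (-8.09 ± 0.62, limma adjusted p = 3.6e-06). It was also negative for WRKY22 (-4.97 ± 0.40), a transcription factor of defence and senescence, LYK5 (-4.86 ± 0.40), a chitin receptor kinase gene, and AAE12 (-3.64 ± 0.30). Jasmonate genes had a negative difference in 14 of 14 members (14 adjusted over the list), with JAZ1 at -5.69 and AOS at -4.09. The median jasmonate difference was -4.49 (camera adjusted p = 9.1e-18, and 0.29 with an estimated correlation). Heat shock genes had a negative difference in 6 of 12 members and had a positive difference in 1 (6 and 1 adjusted over the list), with HSFA2 at -1.83. The median heat shock difference was -0.99 (camera adjusted p = 0.0012, and 0.58 with an estimated correlation). Flavonoid genes had a negative difference in 6 of 16 members and had a positive difference in 2 (7 and 2 adjusted over the list). The median flavonoid difference was -0.51 (camera adjusted p = 0.0060, and 0.58 with an estimated correlation). Pathogen defence genes had a negative difference in 2 of 8 members (2 adjusted over the list). The median pathogen defence difference was -0.84 (camera adjusted p = 0.013, and 0.58 with an estimated correlation). Cytokinin response regulators had a positive difference in 5 of 8 members (7 adjusted over the list), such as ARR7 (1.88). ARR7 fell in wild type and was already lower in cry1cry2 in the dark. The median cytokinin difference was 1.39 (camera adjusted p = 0.0035, and 0.29 with an estimated correlation). Limma called 5727 genes, 3799 with a positive and 1928 with a negative difference. With median-ratio scaling it called 4697, 1896 positive and 2801 negative (median of all genes 0.20 without it). The pathogen defence call was lost without blue-light replicate 2 of wild type (median -0.64, adjusted p = 0.071) or dark replicate 3 of cry1cry2 (-0.68, adjusted p = 0.054). A minimum of FPKM 5 ended that call (-0.53, adjusted p = 0.098) and the flavonoid call (-0.47, adjusted p = 0.061).

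For BIC1ox against wild type, the difference in light response was negative for LAC5, a laccase gene (-3.67 ± 0.30, limma adjusted p = 8.4e-06), the vacuolar invertase gene ATBETAFRUCT4 (-1.92 ± 0.18) and CYP94B1, of jasmonate turnover (-3.66 ± 0.37). It was positive for the cold-response factor gene CBF2 (4.11 ± 0.36) and for MYB27 (2.54 ± 0.24). Jasmonate genes had a negative difference in 12 of 14 members (13 adjusted over the list), with AOC2 at -3.05 and JAZ1 at -2.15. The jasmonate differences had a median of -2.40 (camera adjusted p = 1.5e-08, and 0.42 with an estimated correlation). Chlorophyll synthesis genes had a positive difference in 18 of 25 members (18, and 1 the other way, adjusted over the list), with PORB at 3.24. The chlorophyll differences had a median of 1.29 (camera adjusted p = 0.00011, and 0.87 with an estimated correlation). Light-harvesting genes had a positive difference in 8 of 21 members (12 adjusted over the list), with LHCB6 at 2.65 and LHCA6 at 2.05. The light-harvesting differences had a median of 1.27 (camera adjusted p = 0.0013, and 0.87 with an estimated correlation). Photosystem genes had a positive difference in 7 of 25 members (9 adjusted over the list). The photosystem differences had a median of 0.97 (camera adjusted p = 0.0034, and 0.87 with an estimated correlation). Cytokinin response regulators had a positive difference in 5 of 8 members (7 adjusted over the list), with ARR7 at 1.63. The cytokinin differences had a median of 0.88 (camera adjusted p = 0.0038, and 0.42 with an estimated correlation). Clock genes had a negative difference in 8 of 23 members (11, and 1 the other way, adjusted over the list), with GI at -1.44 and LNK1 at -1.52. The clock differences had a median of -0.46 (camera adjusted p = 0.00011, and 0.42 with an estimated correlation). In the dark LAC5, CBF2 and the clock and chlorophyll lists differed the opposite way (below), so much of these differences lay there. Limma called 5128 genes, 3226 with a positive and 1902 with a negative difference. With median-ratio scaling it called 4755, 1974 positive and 2781 negative (median of all genes 0.15 without it). The count was 2985 when the fit held these 2 genotypes alone and 3332 without dark replicate 2 of BIC1ox. The photosystem call was lost without blue-light replicate 2 of BIC1ox (median 0.66, adjusted p = 0.068). The light-harvesting call was lost when wild-type dark replicate 1, the other library that stood apart, was left out with it (0.64, adjusted p = 0.11).

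The light responses of BIC1ox and cry1cry2 were also set against each other. The difference was positive, BIC1ox minus cry1cry2, for ORA47 (7.42 ± 0.53, limma adjusted p = 3.4e-06), RRTF1 (7.73 ± 0.62) and CBF1 (4.48 ± 0.37). Jasmonate genes had a positive difference in 8 of 14 members (10 adjusted over the list), among them JAZ7 (3.92) and AOS (2.59). The median of the jasmonate differences was 2.34 (camera adjusted p = 8.4e-15, and 0.24 with an estimated correlation). Light-harvesting genes had a positive difference in 4 of 21 members (10 adjusted over the list), with LHCB1.1 at 2.33. The median of the light-harvesting differences was 0.97 (camera adjusted p = 1.6e-11, and 0.32 with an estimated correlation). Photosystem genes had a positive difference in 2 of 25 members (8 adjusted over the list, 4 with median-ratio scaling). The median of the photosystem differences was 1.03 (camera adjusted p = 4.8e-12, and 0.32 with an estimated correlation). Chlorophyll synthesis genes had a positive difference in 2 of 25 members (3 adjusted over the list). The median of the chlorophyll differences was 0.69 (camera adjusted p = 2.3e-09, and 0.32 with an estimated correlation). Clock genes had a negative difference in 10 of 23 members (13 adjusted over the list), with LNK1 at -1.09. The median of the clock differences was -0.76 (camera adjusted p = 2.1e-10, and 0.24 with an estimated correlation). In the dark the medians of these lists other than jasmonate had the opposite sign and similar size (below). Their differences thus lay largely there. Limma called 506 genes, 296 with a positive and 210 with a negative difference. Without blue-light replicate 2 of BIC1ox the light-harvesting, photosystem and chlorophyll medians were 0.64, 0.65 and 0.31. The count rested on single libraries. It was 880 without blue-light replicate 2 and 322 without blue-light replicate 1 of BIC1ox, 311 without its dark replicate 2, 304 without blue-light replicate 3 of cry1cry2 and 332 without dark replicate 1 of cry1cry2.

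**Figure D4:**
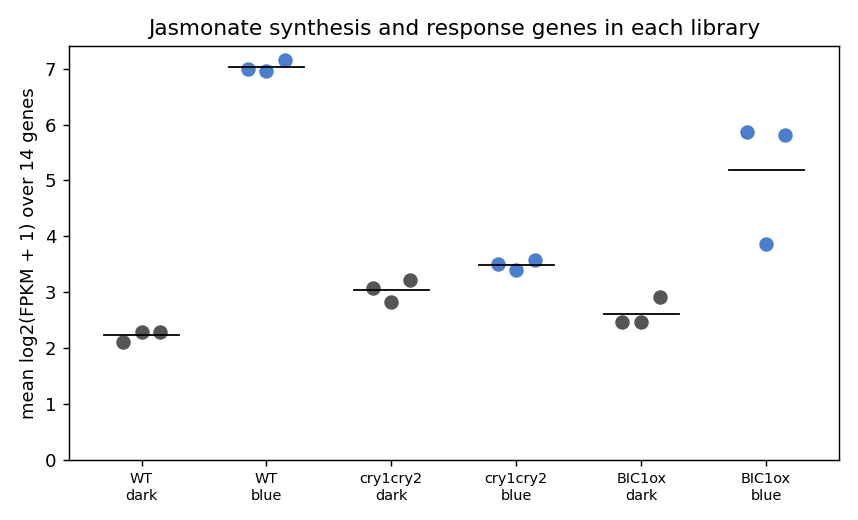
Mean log2(FPKM + 1) of the 14 jasmonate synthesis and response genes in each of the 18 libraries (points), with the mean of each group (bar). The wild-type libraries in blue light lie between 6.95 and 7.15 and the cry1cry2 libraries between 3.39 and 3.58, and 1 BIC1ox library in blue light lies at 3.87, apart from its group mates at 5.81 and 5.87.

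In blue light, cry1cry2 and wild type were compared. RRTF1 (-7.10 ± 0.44), DDF1 (-6.97 ± 0.42) and ORA47 (-5.76 ± 0.37) were lower in cry1cry2 (limma adjusted p = 3.6e-08, 2.8e-08 and 6.1e-08). CYP71A12, CYP71A13 and PAD3, of camalexin synthesis, were higher by 4.80 ± 1.11, 4.08 ± 0.74 and 4.12 ± 0.78. The potassium transporter gene HAK5 was higher by 3.38 ± 0.44 and the auxin-conjugating GH3.2 by 3.32 ± 0.43. The largest fall was that of c-NAD-MDH1 (-7.55 ± 0.13, adjusted p = 5.5e-16), a cytosolic malate dehydrogenase gene that lies next to CRY2. Jasmonate genes were lower in 14 of 14 members (14 adjusted over the list), with JAZ7 at -5.42 and AOS at -3.82. Over the jasmonate list the median was -3.62 (camera adjusted p = 7.1e-21, and 0.16 with an estimated correlation). Flavonoid genes were lower in 11 of 16 members (11 adjusted over the list), with MYB12 at -1.94 and F3H at -1.16. Over the flavonoid list the median was -0.74 (camera adjusted p = 9.2e-09, and 0.16 with an estimated correlation). Oxidative stress genes were lower in 5 of 12 members (5 adjusted over the list), with BAP1 at -2.91. Over the oxidative stress list the median was -0.58 (camera adjusted p = 0.0015, and 0.24 with an estimated correlation). Shade and PIF target genes were higher in 9 of 15 members (10 adjusted over the list), with YUC8 at 1.59 and ATHB4 at 1.37. Over the shade list the median was 0.88 (camera adjusted p = 0.0015, and 0.24 with an estimated correlation). Auxin genes were higher in 22 of 35 members and were lower in 2 (22 and 2 adjusted over the list, 19 and 4 with median-ratio scaling), with SAUR19 at 1.80. Over the auxin list the median was 0.88 (camera adjusted p = 0.0097, and 0.75 with an estimated correlation). Nitrate assimilation genes were higher in 3 of 3 members (3 adjusted over the list), namely NIA1 (1.49), NIA2 (1.34) and NIR1 (0.76). Over the nitrate list the median was 1.34 (camera adjusted p = 0.039, and 0.24 with an estimated correlation). That call was lost without blue-light replicate 1 of wild type (median 1.27, adjusted p = 0.059). Limma called 6781 genes, 5010 higher and 1771 lower in cry1cry2. With median-ratio scaling it called 5031, 2282 higher and 2749 lower (median of all genes 0.22 without it).

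In blue light BIC1ox also differed from wild type in the jasmonate, flavonoid, shade and auxin lists. AT3G44070 (chromosome 3) had 17.3 ± 4.18 FPKM in BIC1ox and 0 reads in each wild-type and cry1cry2 library, so no fold change is given for it. ERF104 was higher by 2.74 ± 0.35, the B-box gene BBX14 by 2.45 ± 0.39 and WRKY70, of salicylic acid signalling, by 2.33 ± 0.34 (limma adjusted p = 0.00018, 0.00083 and 0.00046). The tyrosine aminotransferase gene TAT3 (-3.81 ± 0.67), the glutathione transferase gene GSTU6 (-3.65 ± 0.45) and the ERF gene ABR1 (-3.15 ± 0.47) were lower (limma adjusted p = 0.0016, 0.00014 and 0.00050). With the 6 libraries of these 2 groups alone the adjusted p of TAT3 was 0.059. Jasmonate genes were lower in 11 of 14 members (13 adjusted over the list), with AOC2 at -2.49 and OPR3 at -2.64. Among jasmonate genes the median was -1.90 (camera adjusted p = 1.8e-12, and 0.16 with an estimated correlation). Without replicate 2 of BIC1ox, which stood apart, it was -1.07 (camera adjusted p = 9.1e-19). Flavonoid genes were lower in 6 of 16 members (10 adjusted over the list), with MYB12 at -1.67. Among flavonoid genes the median was -0.60 (camera adjusted p = 9.2e-08, and 0.16 with an estimated correlation). Shade and PIF target genes were higher in 9 of 15 members (10 adjusted over the list), with ATHB4 at 1.03. Among shade genes the median was 0.59 (camera adjusted p = 6.3e-05, and 0.16 with an estimated correlation). Auxin genes were higher in 16 of 35 members (19, and 1 the other way, adjusted over the list), with SAUR23 at 1.39. Among auxin genes the median was 0.53 (camera adjusted p = 6.3e-05, and 0.42 with an estimated correlation). Dark-induced genes were higher in 9 of 16 members (10 adjusted over the list), with DIN2 at 1.55. Among dark-induced genes the median was 0.55 (camera adjusted p = 6.3e-05, and 0.16 with an estimated correlation). Light-harvesting genes were higher in 5 of 21 members (12 adjusted over the list, 1 with median-ratio scaling). Among light-harvesting genes the median was 0.86 (camera adjusted p = 6.3e-05, and 0.66 with an estimated correlation). It was 0.50 without replicate 2 of BIC1ox (camera adjusted p = 0.024). Limma called 2643 genes, 1490 higher and 1153 lower. With median-ratio scaling it called 2718, 1162 higher and 1556 lower. The count was 647 when the fit held these 2 groups alone, 1438 without replicate 2 of BIC1ox and 1723 without replicate 2 of wild type.

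The genes called in both genotypes against wild type were counted. In blue light 2102 genes were called in the same direction in cry1cry2 and BIC1ox, 1262 higher and 840 lower, and 26 in opposite directions. Independent lists of these sizes would share 390.2 and 107. In the dark 3801 were called in the same direction, 1746 higher and 2055 lower, and 31 in opposite directions, against 487 and 579 for independent lists. Both comparisons use the same wild-type libraries. Simulated unchanged groups against those controls shared a mean of 0 genes over 100 draws. With no change put in, this cannot show how many shared calls the common controls add. The log2 fold changes correlated across genes, which are not independent replicates, with r = 0.666 in blue light and 0.699 in the dark, against 0.500 and 0.499 in the simulation. Their covariance was 0.218 and 0.254 against 0.0228 and 0.0227. With the controls split, 1 library for one genotype and 2 for the other in 6 ways, 361 to 1150 genes were shared in blue light and 493 to 2829 in the dark. The covariance then averaged 0.188 and 0.211, and r 0.519 and 0.542. The blue-light overlap was 1188 without replicate 2 of BIC1ox, 1376 without replicate 2 of wild type and 543 with fits of the groups of each contrast alone.

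In the dark cry1cry2 differed from wild type in cytokinin and heat shock genes. The pathogen defence list was not called (median 1.08, camera adjusted p = 0.060; 4 of 8 members higher, 4 adjusted over the list). The camalexin genes CYP71A12 (6.26 ± 1.11, limma adjusted p = 0.00080) and CYP71A13 (5.49 ± 0.74) and the indole glucosinolate gene CYP81F2 (4.87 ± 0.84) were higher in cry1cry2 in the dark. The glutathione transferase gene GSTF6 (4.91 ± 0.98) was higher too. Lower genes beside CRY1 and CRY2 were c-NAD-MDH1 (-8.85 ± 0.13), the heat stress factor gene HSFA6B (-3.51 ± 0.45), CBF2 (-2.67 ± 0.25) and CHS (-2.62 ± 0.23). AT1G04420 and the arginase gene ARGAH1 were listed at 0 in each cry1cry2 library in the dark. Cytokinin response regulators were lower in 8 of 8 members (8 adjusted over the list), with ARR7 at -2.12 and ARR4 at -1.30. Across cytokinin genes the median was -0.82 (camera adjusted p = 0.00015, and 0.14 with an estimated correlation). Heat shock genes were higher in 7 of 12 members (7 adjusted over the list), with HSP17.6A at 1.96. Across heat shock genes the median was 0.61 (camera adjusted p = 0.0035, and 0.75 with an estimated correlation). Seed storage and late embryogenesis markers, listed as signs of other tissue, were higher in 3 of 13 members (3 adjusted over the list), with EM1 at 2.29 and SESA1 at 4.42. Across seed genes the median was 1.67 (camera adjusted p = 0.013, and 0.87 with an estimated correlation). The call of SESA1 was lost by limma voom (5.64, adjusted p = 0.11). Photosystem genes were higher in 10 of 25 members (10 adjusted over the list), with PSAH2 at 1.36. Across photosystem genes the median was 0.58 (camera adjusted p = 0.013, and 0.90 with an estimated correlation). Shade and PIF target genes were higher in 7 of 15 members (8, and 1 the other way, adjusted over the list), with ATHB2 at 2.41. Across shade genes the median was 0.56 (camera adjusted p = 0.036, and 0.75 with an estimated correlation). Nitrate assimilation genes were higher in 2 of 3 members (2 adjusted over the list), with NIA2 at 2.44. Across nitrate genes the median was 1.75 (camera adjusted p = 0.036, and 0.51 with an estimated correlation). Without replicate 3 of wild type the seed, photosystem, shade and nitrate calls were lost (medians 1.56, 0.55, 0.49 and 1.62, adjusted p = 0.063, 0.083, 0.063 and 0.088). The photosystem call was also lost without replicate 2 of cry1cry2 (0.46, adjusted p = 0.083), the shade and nitrate calls without its replicate 3 (0.43 and 1.65, adjusted p = 0.054) and the nitrate call without replicate 2 of wild type (1.75, adjusted p = 0.080). The shade median was 0.33 without replicate 1 of wild type. Limma called 6455 genes, 3521 higher and 2934 lower (6407 with median-ratio scaling, 3438 and 2969), and 3226 when the fit held these 2 groups alone. Quantile normalization turned the majority (6599, 3025 higher and 3574 lower). The fold changes of this contrast rose with gene length (Spearman rho = 0.237, with medians from -0.14 under 500 bases to 0.23 at 2500 or more), more than in any other. With that trend removed 5957 genes were called, and the cytokinin and heat shock medians were -0.67 and 0.67 (camera adjusted p = 0.00019 and 0.0011). Wild-type replicate 1 stood apart, with 191 CPM in microRNA genes against 75.1 and 72.6 in its group mates. Without it these medians were -0.76 and 0.73.

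In the dark BIC1ox differed from wild type in clock, chlorophyll and auxin genes. Apart from BIC1 and AT3G44070 (24.7 ± 0.987 FPKM in BIC1ox), LAC5 (3.67 ± 0.21), EPR1 (3.06 ± 0.61) and the lipid transfer protein gene LTP3 (3.05 ± 0.23) were higher (limma adjusted p = 3.5e-08, 0.0021 and 1.6e-06). HSFA6B (-3.15 ± 0.45), ESM1 (-2.68 ± 0.25), CBF2 (-2.45 ± 0.25) and CHS (-2.44 ± 0.23) were lower. Clock genes were higher in 14 of 23 members (14 adjusted over the list), with GI at 1.35, LNK1 at 1.51 and PRR5 at 1.27. For clock genes the median was 0.68 (camera adjusted p = 1.1e-07, and 0.27 with an estimated correlation). Chlorophyll synthesis genes were lower in 14 of 25 members and were higher in 1 (15 and 1 adjusted over the list), with PORB at -1.59 and GSA2 at -1.68. For chlorophyll genes the median was -0.92 (camera adjusted p = 0.0011, and 0.78 with an estimated correlation). Auxin genes were higher in 15 of 35 members and were lower in 4 (18 and 4 adjusted over the list, 18 and 1 with median-ratio scaling), with GH3.5 at 2.05 and TAA1 at -1.17. For auxin genes the median was 0.68 (camera adjusted p = 0.00029, and 0.38 with an estimated correlation). Dark-induced genes were higher in 9 of 16 members (10, and 1 the other way, adjusted over the list), with DIN2 at 2.24. For dark-induced genes the median was 0.55 (camera adjusted p = 0.00029, and 0.27 with an estimated correlation). The auxin median was 0.43 without replicate 1 of wild type. Limma called 6417 genes, 2644 higher and 3773 lower. With median-ratio scaling it called 6171, 3384 higher and 2787 lower. The count was 3404 when the fit held these 2 groups alone and 4148 without replicate 2 of BIC1ox.

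BIC1ox and cry1cry2 were compared directly in each light. In blue light c-NAD-MDH1 (7.45 ± 0.13), ORA47 (7.29 ± 0.37), RRTF1 (6.53 ± 0.44) and CBF1 (4.70 ± 0.26) were higher in BIC1ox. CYP71A12 (-5.24 ± 1.11), CYP71A13 (-4.66 ± 0.74) and PAD3 (-4.58 ± 0.78) were lower, with limma adjusted p of 0.0054, 0.00061 and 0.0010. Jasmonate genes were higher in 7 of 14 members (12 adjusted over the list), with JAZ7 at 4.06 and MYC2 at 2.17. Here the jasmonate median was 1.68 (camera adjusted p = 5.9e-14, and 0.28 with an estimated correlation). Nitrate assimilation genes were lower in 3 of 3 members (3 adjusted over the list), with NIA1 at -1.93. Here the nitrate median was -1.13 (camera adjusted p = 0.00064, and 0.12 with an estimated correlation). In the dark c-NAD-MDH1 (8.13 ± 0.13), LTP3 (3.17 ± 0.23) and the sucrose phosphate synthase gene SPS2F (2.52 ± 0.21) were higher, and CYP71A13 (-4.30 ± 0.74) was lower. Clock genes were higher in 12 of 23 members (13 adjusted over the list), with LNK3 at 2.09 and RVE8 at 0.99. The clock genes had a median of 0.71 (camera adjusted p = 4.4e-14, and 0.044 with an estimated correlation). Photosystem genes were lower in 10 of 25 members (15 adjusted over the list), with PSAH2 at -1.96. The photosystem genes had a median of -0.96 (camera adjusted p = 3.8e-07, and 0.37 with an estimated correlation). Light-harvesting genes were lower in 10 of 21 members (11, and 1 the other way, adjusted over the list), with LHCA1 at -2.13. The light-harvesting genes had a median of -0.91 (camera adjusted p = 2.3e-06, and 0.37 with an estimated correlation). Chlorophyll synthesis genes were lower in 8 of 25 members (16, and 1 the other way, adjusted over the list, 5 with median-ratio scaling), with PORC at -1.38. The chlorophyll genes had a median of -0.69 (camera adjusted p = 2.3e-06, and 0.37 with an estimated correlation). Nitrate assimilation genes were lower in 3 of 3 members (3 adjusted over the list), with NIA1 at -1.95. The nitrate genes had a median of -1.68 (camera adjusted p = 9.5e-05, and 0.044 with an estimated correlation). Seed markers of other tissue were lower in 3 of 13 members (5 adjusted over the list). The seed genes had a median of -1.61 (camera adjusted p = 0.010, and 0.51 with an estimated correlation). That call was lost without replicate 1 of BIC1ox (-0.60, adjusted p = 0.52). Limma called 1949 genes in blue light, 667 higher and 1282 lower (1674 with median-ratio scaling, 960 and 714, and a median of all genes of -0.13 without it). It called 1859 in the dark, 679 higher and 1180 lower (1709 with median-ratio scaling, 923 and 786). The blue-light count was 1141 without replicate 1 of cry1cry2 and 1251 without replicate 1 of BIC1ox. The dark count was 735 without replicate 2 of BIC1ox and 971 and 1229 without replicates 1 and 3 of cry1cry2.

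Some genes that lie beside the CRY loci were, like CRY1 and CRY2, near 0 in cry1cry2. A search made after the values were seen looked for genes at least 50-fold lower in cry1cry2 in both lights among 12770 genes with a wild-type mean of at least FPKM 5. It found 5 genes: CRY1, CRY2, c-NAD-MDH1, AT1G04420 and ARGAH1. ARGAH1 (AT4G08900, chromosome 4) had 11.2 ± 2.1 FPKM in wild type in the dark and was listed at 0 in cry1cry2 in the dark. It had 8.81 ± 1.76 and 0.0192 ± 0.0167 FPKM in blue light. The gene next to CRY2 in the annotation, c-NAD-MDH1 (AT1G04410, chromosome 1), had 523 ± 74.1 and 259.5 ± 19.4 FPKM in wild type and 0.127 ± 0.0278 and 0.393 ± 0.158 in cry1cry2. AT1G04420, the gene after it, had 27.2 ± 3.40 and 11.4 ± 2.98 FPKM against 0 and 0.0365 ± 0.0429. AT4G08910, the annotated gene between ARGAH1 and CRY1, also singled out after its values were seen, had 70 reads over the wild-type, 75 over the BIC1ox and 0 over the cry1cry2 libraries. In BIC1ox a search with the same bounds found BIC1 and AT3G44070, with 1450 reads of AT3G44070 in the dark and 1079 in blue light. Whether these reads come from that locus or from the transgene was not tested.

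**Figure D5:**
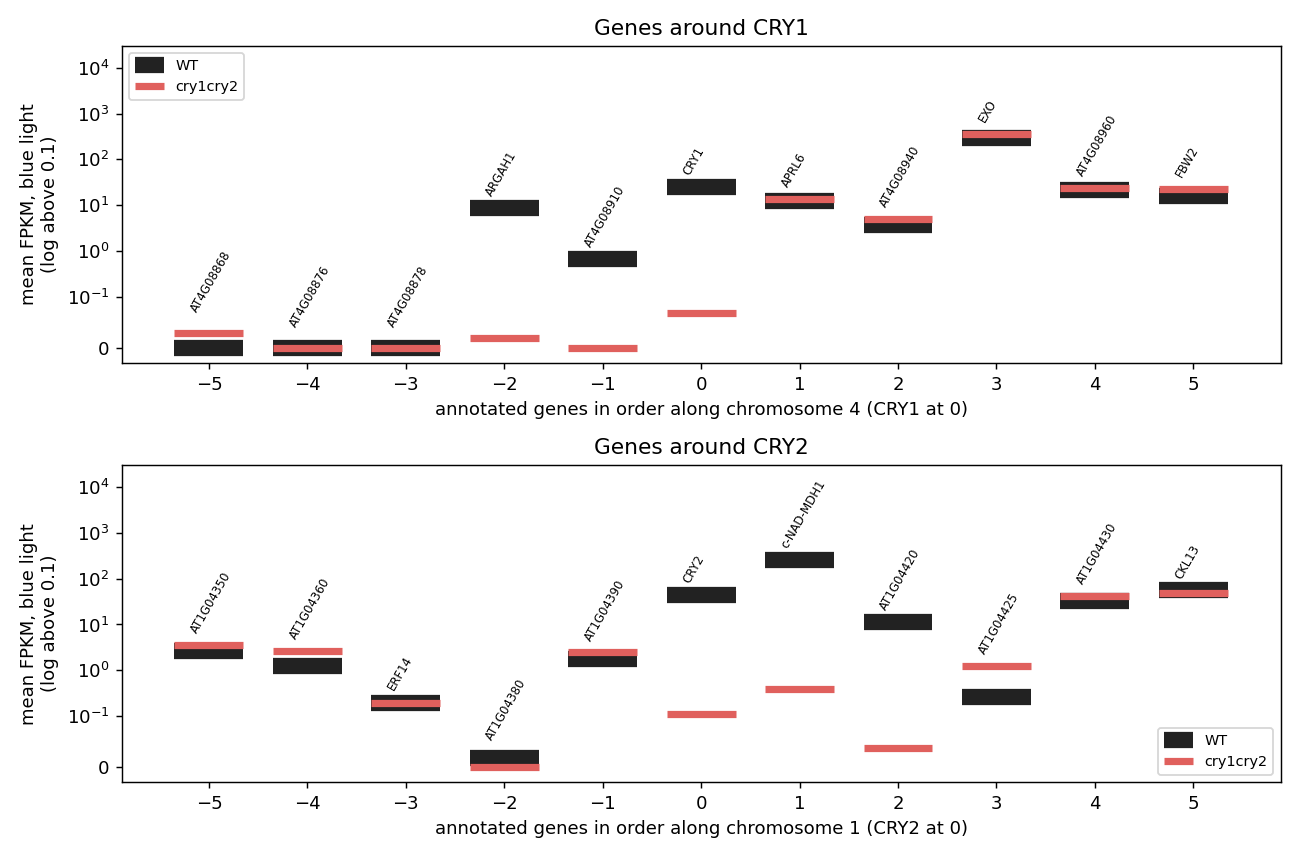
Mean FPKM in blue light (logarithmic above 0.1, linear below; 3 libraries per group) of CRY1 (upper map) and CRY2 (lower map) and of 5 annotated genes on each side, in their order along chromosomes 4 and 1, in wild type (thick bars) and cry1cry2 (thin bars). ARGAH1, AT4G08910 and CRY1, and CRY2, c-NAD-MDH1 and AT1G04420, lie near 0 in cry1cry2.

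The deposited table also holds the authors' own test of blue light against dark per genotype. At their false discovery rate under 0.05 it marks 8426 genes in wild type (4537 higher, 3889 lower), 5748 in cry1cry2 (2867 and 2881) and 4998 in BIC1ox (2962 and 2036). Of those also tested here, limma called 93.5%, 63.2% and 88.4%. The authors' test is not stated.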

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

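The tests that weigh the 3 patterns below, and the relabelings for the difference between cry1cry2 and wild type, were chosen only after the results were seen, and the permutations of residuals after the relabelings were seen. Each result listed stood out because 2 light responses differed by limma's test of the difference. Groups of 3 were not tested for a single outlying library.

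The light response of cry1cry2 differed from that of wild type for 5727 genes. The 10 genes with the smallest adjusted p were RRTF1 (-8.09), WRKY22 (-4.97), LYK5 (-4.86), AT4G27654 (-4.71), AT2G35290 (-4.01), AT1G75000 (-3.66), AAE12 (-3.64), AT5G02940 (-2.54), AT3G27809 (-1.76) and AT3G13404 (2.3). AT3G27809 was listed at 0 in cry1cry2 and in wild type in the dark, so its value depends on the constant added. Lists called by camera had median differences of -4.49 (jasmonate), -0.99 (heat shock), -0.84 (pathogen defence), -0.51 (flavonoid), -0.27 (oxidative stress) and 1.39 (cytokinin). With an estimated correlation none of these calls held (adjusted p = 0.29 to 0.58). The oxidative stress median was -0.40 without blue-light replicate 1 of wild type. The pathogen defence call was lost without single libraries given above (-0.64 and -0.68).

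The light response of BIC1ox differed from that of wild type for 5128 genes, or 3332 without dark replicate 2 of BIC1ox. The 10 genes were BIC1 (-3.76), LAC5 (-3.67), CYP94B1 (-3.66), AT5G53050 (-2.35), ATBETAFRUCT4 (-1.92), AT3G27809 (-1.67), SAT32 (-1.60), MYB27 (2.54), AT3G13404 (2.57) and CBF2 (4.11). The list medians were -2.40 (jasmonate), -0.66 (flavonoid), -0.46 (clock), -0.25 (early light), 0.88 (cytokinin), 0.97 (photosystem), 1.27 (light-harvesting) and 1.29 (chlorophyll). With an estimated correlation none of these calls held (adjusted p = 0.42 to 0.87). Without blue-light replicate 2 of BIC1ox the photosystem call was lost (0.66) and the early light median was -0.15, or -0.14 without its dark replicate 2. With dark replicate 1 of wild type left out too, the light-harvesting call was lost (0.64).

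The light responses of BIC1ox and cry1cry2 differed for 506 genes. Without 1 library the count ranged from 304 to 880. The 10 genes were RRTF1 (7.73), ORA47 (7.42), AT1G19210 (5.84), AT4G29780 (5.29), AT4G27654 (4.91), CBF1 (4.48), AT2G30020 (4.05), NUDT4 (3.98), AT1G74450 (3.75) and BIC1 (-3.31). The list medians were 2.34 (jasmonate), 0.97 (light-harvesting), 1.03 (photosystem), 0.69 (chlorophyll), -0.76 (clock) and -0.56 (auxin), and none of these calls held with an estimated correlation (adjusted p = 0.24 to 0.32). The light-harvesting, photosystem and chlorophyll medians were 0.64, 0.65 and 0.31 without blue-light replicate 2 of BIC1ox. Heat shock genes had a median of 0.49 (camera adjusted p = 0.00040, and 0.32 with an estimated correlation). The oxidative stress median was -0.087, while its mean was 1.04 and camera called it higher in BIC1ox (camera adjusted p = 0.0049, and 0.32 with an estimated correlation); without 1 library the median ranged from -0.13 to 0.052. For pathogen defence the median was 0.98 (camera adjusted p = 0.00032, and 0.32 with an estimated correlation), with 0 members called by limma, 5 at unadjusted p under 0.05 and 0 by limma voom. For carotenoids it was 0.46 (camera adjusted p = 0.0068, and 0.72 with an estimated correlation), with 0 members called by limma, 3 at unadjusted p under 0.05 and 0 by limma voom. That call was lost without blue-light replicate 2 of BIC1ox (0.17) or dark replicate 2 of cry1cry2 (0.40), and the median was 0.70 without blue-light replicate 3 of BIC1ox.

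Other arrangements of the same libraries were tried. In each contrast between 2 groups, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes. These splits are too few for a share under 0.05. The highest of the others called 0 genes in the light response of wild type (11618 in the real split), 1 in that of cry1cry2 (3538) and 42 in that of BIC1ox (5836). It called 0 for cry1cry2 against wild type in blue light (6781) and 1 in the dark (6455), 0 for BIC1ox against wild type in blue light (2643) and 5 in the dark (6417), and 0 for BIC1ox against cry1cry2 in blue light (1949) and 3 in the dark (1859). Of the 4 splits of the cry1cry2 libraries that part the 3 pairs of equal number, the highest other called 0. For the differences between light responses, dark and blue-light labels were redrawn within genotypes 100 times. As many genes were called in 10 draws for cry1cry2 against wild type (highest other 10803), 10 for BIC1ox against wild type (8920) and 11 for BIC1ox against cry1cry2 (7321), so chance was not excluded by these draws. Each of the 9, 9 and 10 other draws kept the split of at least 1 genotype intact. Those with 10803 and 7321 genes kept both splits, with dark and blue light exchanged in 1 genotype. Among the 74, 75 and 79 draws that kept none intact, at most 0, 3 and 15 genes were called. Permuting the residuals after removal of the light and genotype effects gave as many genes in 1 of 100 draws each, the real one (highest other 1422, 2406 and 468), which excludes chance by this test. For BIC1ox against cry1cry2 this exclusion is weak, with 506 genes against 468, and 304 without 1 library.

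Genes changed by at least 1 (log2) in wild type had smaller responses in the other genotypes (median ratio 0.261 in cry1cry2, 0.408 in BIC1ox). Had a single library, gene length or scaling been the whole cause, the higher ratio would have passed 0.75. It was 0.473 without wild-type dark replicate 1, 0.435 without the length trend and 0.430 with median-ratio scaling (SD 0.0871 over replicate pairings). In the dark cry1cry2 and BIC1ox also differed from wild type (6455 and 6417 genes), so a deviating wild-type dark group could lower both ratios. That, unrecorded growth differences and, in cry1cry2, the loss of c-NAD-MDH1, ARGAH1 and AT1G04420 were not tested and stay open. So does a weaker light response without cryptochromes or with excess BIC1.

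Jasmonate genes rose in wild type and BIC1ox and were not called as a list in cry1cry2. Their mean log2(FPKM + 1) still rose there in each equally numbered pair (3.08 to 3.51, 2.82 to 3.39, 3.21 to 3.58). A single library was argued against by the median difference between cry1cry2 and wild type, nearest to 0 at -4.44 over the 12 fits without 1 library. The scaling was argued against by -4.70 with median-ratio scaling. Handling at harvest, such as wounding, could raise these genes in a whole group. The blue-light list means ranged over 2.001 in BIC1ox, 0.204 in wild type and 0.192 in cry1cry2, and the latter genotypes lay 3.37 apart. Handling and a role of cryptochromes cannot be told apart, because each group may have been harvested at once. The loss of genes beside CRY1 and CRY2 (below) was not tested as a cause.

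Genes next to CRY1 and CRY2 were near 0 in cry1cry2. Chance placement was argued against by a hypergeometric p of 1.2e-11 for the 3 other lost genes lying within 2 annotated genes of either locus, a distance chosen after the loss was seen. Reads of CRY2 counted for its neighbour were argued against as well, since c-NAD-MDH1 had 7.53 times the FPKM of CRY2 in wild type in the dark. AT4G08910, between ARGAH1 and CRY1, had 0 reads where 68.5 were expected from wild type, but this had been seen before the test was written and is no independent evidence for a lesion that takes in the neighbours. Mutations that reach beyond CRY1 and CRY2 stay open as a hypothesis that needs the DNA sequence, not analysed here.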

How the results depend on the processing

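Leaving out both libraries that stood apart, limma voom on recovered reads, the gene-length correction, the replicate block within each genotype and the split controls were chosen only after the results were seen. Over all alternatives, counts of changed genes stayed within 1.5 times the reported count in 195 cases and left that range in 33, the overlap in 16 and 10, and the medians and ratios of the wild-type light-responsive genes moved by less than the spread between replicates in 55 and by more in 1. Named genes kept their side of the threshold in 18913 cases, lost a call in 1233 and gained one in 246. Lists did so in 5547, 167 and 116, with 2 reversed. DESeq2 and edgeR, set only for raw counts, were not used because the table held FPKM. Recovered reads were tested with limma voom only. Depth limits genes with few reads, for which 0 reads allow up to 3.

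Fits of the groups of the contrast alone have fewer residual degrees of freedom and use the spread of those groups only. They called 5370 genes for the light response of cry1cry2, whose groups varied least, where the joint fit called 3538. They called 647 for BIC1ox against wild type in blue light and 3404 in the dark, and 3226 for cry1cry2 against wild type in the dark. They called 2985 for the light response of BIC1ox minus that of wild type, with an overlap of 543. An absolute log2 fold change of at least 1, which by construction leaves fewer genes, left 4549, 1122 and 2008 for the light responses of wild type, cry1cry2 and BIC1ox. It left 1956 and 1754 for cry1cry2 against wild type in blue light and in the dark, 786 and 1386 for BIC1ox against wild type, 833 and 711 for BIC1ox against cry1cry2, 2755 and 2531 for the light responses of cry1cry2 and BIC1ox minus that of wild type, and an overlap of 577.

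Without the libraries that stood apart, dark replicate 1 of wild type and blue-light replicate 2 of BIC1ox, counts were 3597 for BIC1ox against cry1cry2 in blue light, 3738 in the dark and 1247 for the difference of their light responses, and the median ratio of BIC1ox to wild type was 0.544. The cause was not tested. The median of light-harvesting genes in BIC1ox against cry1cry2 in blue light (0.079, camera adjusted p = 0.046) was reversed to -0.25 in that fit and also without blue-light replicate 2 of BIC1ox alone (camera adjusted p = 0.63 and 0.59). Without 1 library it ranged from -0.25 to 0.32.

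With 1 library left out, the lone pair of its group is assumed to vary like the other groups. Counts then ranged from 10512 to 11152 for the light response of wild type, 2540 to 3213 for cry1cry2 and 4597 to 5236 for BIC1ox. For cry1cry2 against wild type they ranged from 4729 to 6442 in blue light and 4463 to 6740 in the dark. For BIC1ox against wild type they ranged from 1438 to 3123 in blue light and from 4148 to 6592 in the dark. For BIC1ox against cry1cry2 they ranged from 1141 to 2421 in blue light and from 735 to 1476 in the dark. Differences from the wild-type response ranged from 4479 to 5954 for cry1cry2 and from 3332 to 5519 for BIC1ox. Those between BIC1ox and cry1cry2 ranged from 304 to 880. The overlap ranged from 1188 to 2416. With the wild-type controls split between the comparisons it was 965, 951 and 1069 with replicate 1, 2 or 3 alone for cry1cry2, and 361, 540 and 1150 with these alone for BIC1ox. The cause was not tested.

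With the replicate number as a replicate block, 3329 genes were called in the light response of cry1cry2, where equal numbers paired the libraries, and 2853 with a block within each genotype. With the replicate block across genotypes, 11438 genes were called in the light response of wild type and 5585 in that of BIC1ox. No count moved by over 1.5 times under either block. The call of CRY2 in the light response of BIC1ox was lost with the block within each genotype (-0.35, limma adjusted p = 0.089).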

Other observations

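Genes of light reception and hormones moved both ways in wild type after 2 h of blue light, and camera called none of the lists named here. Of 14 photoreceptor genes 3 rose and 8 fell (median -0.48, camera adjusted p = 0.67). CRY3 rose by 3.47 ± 0.17 and the phototropin gene PHOT2 by 1.49 ± 0.15, while PHOT1 (-1.72 ± 0.12) and the phytochrome gene PHYA (-1.56 ± 0.15) fell (n = 3 per group, limma adjusted p = 3.6e-10, 5.6e-07, 8.5e-09 and 3.2e-07). Among 9 PIF and phytochrome A transport genes 3 rose, such as PIF7 (2.18), and 2 fell, such as FHY1 (AT2G37678, -3.66; median -0.15, mean 0.01, camera adjusted p = 0.42). The flowering time list had 2 rises, with CDF1 (AT5G62430) at 2.76, and 4 falls, with CIB4 at -1.38 (median -0.79, camera adjusted p = 0.78, 6 members). Of 19 gibberellin genes 8 rose, with GA2OX1, of gibberellin breakdown, at 3.55, and 9 fell, with GAI at -2.43 (median -0.15, mean 0.26, camera adjusted p = 0.35). Of 8 brassinosteroid genes 2 rose and 4 fell, with BAS1 at -2.02 (median -0.24, 0.02 with median-ratio scaling, camera adjusted p = 0.79).

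Camera called none of the lists of growth genes and markers of other tissues. Of 17 cell wall expansion genes 5 rose, with XTH22 at 3.22, and 5 fell, with XTH15 at -4.25 (median 0.07, mean -0.07, camera adjusted p = 0.59). Of 15 cell cycle genes 7 fell, with KNOLLE at -0.95 (median -0.29, camera adjusted p = 0.56). Of 13 root markers 2 rose and 2 fell (median -0.08, mean 0.04, camera adjusted p = 0.46), and of 9 stomatal markers 2 rose (median 0.08, camera adjusted p = 0.32). Limma called 0 of 13 seed markers, with 0 at unadjusted p under 0.05 and 0 by limma voom (median 0.40, camera adjusted p = 0.33). Adjusted over the list the counts were the same, except for 9 falls among photoreceptors and 1 among root markers. With median-ratio scaling 2 cell cycle genes rose and 2 fell, 3 brassinosteroid genes rose and 2 fell, 8 cell wall genes rose and 5 fell, and 4 root markers rose and 1 fell. With that scaling the PIF (0.09), gibberellin (0.13) and root (0.21) medians were above 0.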
